A study of Rattus norvegicus with 6 samples.

How the data were processed

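Total RNA of cultured primary rat astrocytes was extracted with a column kit, amplified to biotin-labelled RNA and hybridised to Illumina rat beadchips, per the labels' protocols. The 6 arrays were 3 of GFAP-tTA/TRE-TDP43 M337V cells and 3 of GFAP-tTA cells, 1 per genotype at 3, 4 and 6 days after Dox withdrawal. The signals were exported with GenomeStudio, per the submitters' processing notes, and its version is not given in the sources used here. Per the file headers, the deposited table of unprocessed values holds for each array a mean bead signal intensity per probe, on a linear scale and not normalized. The same table holds, per the file headers, a detection p-value for each probe and array, which sets the probe against negative control beads. The deposited value table holds log2 values. Set against the signals, its differences between arrays equal log2 signal minus each array's upper quartile, within 0.00215. A further value per probe was subtracted by the authors that is not the median of these 6 arrays, since that median is 0 (within 0.00001) for only 1964 of 22523 probes, so the centring of the deposited values is unknown. Column medians of that table lay between -0.15 and 0.07. Each column was given to its array by the sample name in the labels or by the sample it belongs to, and no column was left over.

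Probes were named from GEO's platform annotation, in which 13793 probes have 1 gene symbol. The other 8730 are left unnamed here, and any probe listed with several symbols is among them. The Entrez identifiers of 13752 probes matched NCBI's current rat gene table (assembly GRCr8, used only for names), 41 did not match and keep the platform's symbol, and no symbol changed. The named probes cover 13337 genes. The main values were made with limma 3.58.1 in R 4.3.3. Background was corrected with normexp, with the background's mean and spread inferred from the detection p-values (neqc), an offset of 16 was added, arrays were quantile-normalized and log2 was taken. The offset and the background correction shrink or widen the differences of dim genes, so a fold is a fold of normalized signal. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (10478 probes), and each gene is represented by its probe of highest mean level, which left 7580 genes. Of 125 genes with several such probes, 0 had probes called in opposite directions and 23 had some called and others not. Signals were a mean of 377 to 554 per array and 43.8% to 48.3% of the probes were detected, so changes among the other probes are bounded by background. Where no array of a group detected a gene, the text gives "at least N-fold", the brighter group's mean over the dimmer group's mean of the higher of its own signal and each array's lowest detected signal, on the normalized log2 scale. The same bound is given for the genes named with the largest differences, and for some list members, where only some arrays of the dimmer group detected them.

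The genotype effect was fitted with lmFit and eBayes, with the day as a factor and the genotype, which leaves 2 residual degrees of freedom (prior 3.53). The day is shared by the array pairs, per the labels, and pairs of the same day deviated together from their group means across genes (correlations 0.44, 0.08 and 0.42 on days 3, 4 and 6), with all 6 arrays correlating best with the array of their own day. The same fit gave the day effect, day 6 minus day 3 over both genotypes. The slope of the genotype difference per day was fitted with 1 residual degree of freedom (prior 4.71). Benjamini-Hochberg adjustment was over all genes tested, with a threshold of 0.05. The difference at each day has no test. It counts genes at least 2-fold apart among those detected on either array. The 33 gene lists came from textbook knowledge of astrocytes, other brain cells and pathways, and 639 of their 775 entries match a gene on the array. Each list had at least 5 members tested, and camera was run with an inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. With an estimated correlation camera takes the residual degrees of freedom, 2 here and 1 for slopes. A list that does not pass there may fail for that reason alone. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule names the 12 largest rises and falls among called genes of the same sign on all days, then Tardbp, Gfap, Lcn2 and Chi3l1, up to 4 members per list with the largest differences, 3 rises and 3 falls per day, 5 positive and 5 negative slopes by smallest p because none passed, and 6 rises and 6 falls with day. Those with day were taken only from called genes of the same sign in both genotypes.

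The fits were tested on simulated data with 200 of 7580 genes changed. The genotype fit recovered 0 of 200 genes at a log2 change of 0.5, 170 at 1 (with 11 false calls) and 198 at 2 (with 4 false calls). In the arrays 19.6% of the genes were called, a larger share than was changed here. The adjusted threshold is easier to pass with more changed genes, so these rates do not carry over. The slope fit recovered 55.5% at 0.5 per day and 98.5% at 1 per day. With no change, 0 of 33 lists were called, and a list shifted by 0.5 was called. The simulated genes varied independently of each other, so this does not show how the list test behaves where members vary together. In the arrays the estimated correlation differed between lists and was 0.37 for microglia and 0.60 for mature astrocyte genes. Alternatives were no background correction, the deposited values, cyclic loess, median scaling, an offset of 50, no filter, detection on all 6 arrays, no replicate block, the day as a linear covariate, a variance trend, robust eBayes, a threshold of 0.10, a minimum log2 difference of 1, the mean of a gene's probes, each day left out, a 1.5-fold threshold and the other list tests. For single genes only the adjusted p was set against the threshold. The minimum log2 difference of 1 and the threshold of 0.10 changed counts of genes but could end no gene's call. Tests of every detected probe with or without a name, and of the lists without microglia genes, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.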

Results

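Gene expression was measured on Illumina beadchips in cultured primary rat astrocytes of 2 genotypes. The M337V group, 3 arrays, came from rats carrying both a GFAP-tTA and a TRE-TDP43 transgene, and the tTA control group, 3 arrays, came from rats carrying GFAP-tTA alone. TDP-43, the product of Tardbp, is an RNA-binding protein whose M337V substitution is linked to amyotrophic lateral sclerosis. tTA is a transcription factor that drives the TRE promoter once doxycycline (Dox) is taken away, so withdrawal of Dox switches the mutant transgene on in the double transgenic cells. RNA was taken 3, 4 or 6 days after withdrawal, with 1 array per genotype and day. The number of arrays limits the precision, and the labels do not say whether the arrays of a genotype came from separate cultures. In the main fit the p-values measure how the M337V minus control difference varied between the 3 days, not between known replicate cultures. If each genotype was 1 culture sampled over time, the genotype cannot be told apart from a difference between cultures. The spread behind every p-value and SE given is moderated by eBayes, which draws each gene toward the spread of all genes. The prior had 3.53 degrees of freedom against 2 residual, and 4.71 against 1 for slopes, so the SE rest largely on the other genes.

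Each array held 22523 probes. The mean signal was 481, 468 and 474 on the control arrays of days 3, 4 and 6 and 377, 526 and 554 on the M337V arrays of the same days. Between 9856 and 10873 probes per array were detected above background. After normalization, arrays of the same genotype correlated at 0.979 to 0.992 across the genes tested. Arrays of different genotypes correlated at 0.932 to 0.972. The first principal component held 70.0% of the variance and separated the genotypes. Scores ran from -0.50 to -0.29 on the control arrays and from 0.22 to 0.58 on the M337V arrays.

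The design first asks how astrocytes with induced mutant TDP-43 differ from control astrocytes of the same day. The rat Tardbp probe (ILMN_1376454) read 11.20, 11.23 and 10.83 (log2 of normalized signal) on the M337V arrays of days 3, 4 and 6 and 11.08, 10.87 and 10.62 on the control arrays. The difference of 0.23 ± 0.10 (SE, n = 3 days) did not pass (adjusted p = 0.187), except with a variance trend (0.046; over all alternatives 0.046 to 0.584). Whether this probe can bind the transcript of the transgene is not given in the sources used here, so its level checks nothing about the labels. Gfap, the intermediate filament gene whose promoter drives tTA, differed by 0.06 ± 0.10 (adjusted p = 0.724). That value changed sign with the normalization (-0.11 with the deposited values and -0.03 with median scaling), and its probe is among the brightest on the array, where quantile normalization gives all arrays nearly the same values. Lcn2, a secreted iron-binding protein of reactive astrocytes, was 2.99-fold higher in M337V (log2 difference 1.58 ± 0.14, adjusted p = 0.00239). Chi3l1, a secreted glycoprotein of the chitinase family, was 1.66-fold higher (log2 difference 0.73 ± 0.17, adjusted p = 0.0401). Without the replicate block, which here is the day, neither passed (adjusted p = 0.0547 for Lcn2 and 0.576 for Chi3l1, the highest over their alternatives). The lowest were 1.71e-08 and 0.00123. The change of these genes from day 3 to day 6 (1.20 and 2.41) stays in the residual spread of the fit without the block. The call of Chi3l1 was also lost without the filter on dim probes (adjusted p = 0.0553), with the day as a linear covariate (0.115), without day 3 (0.0832) and without day 4 (0.12).

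**Figure D1:**
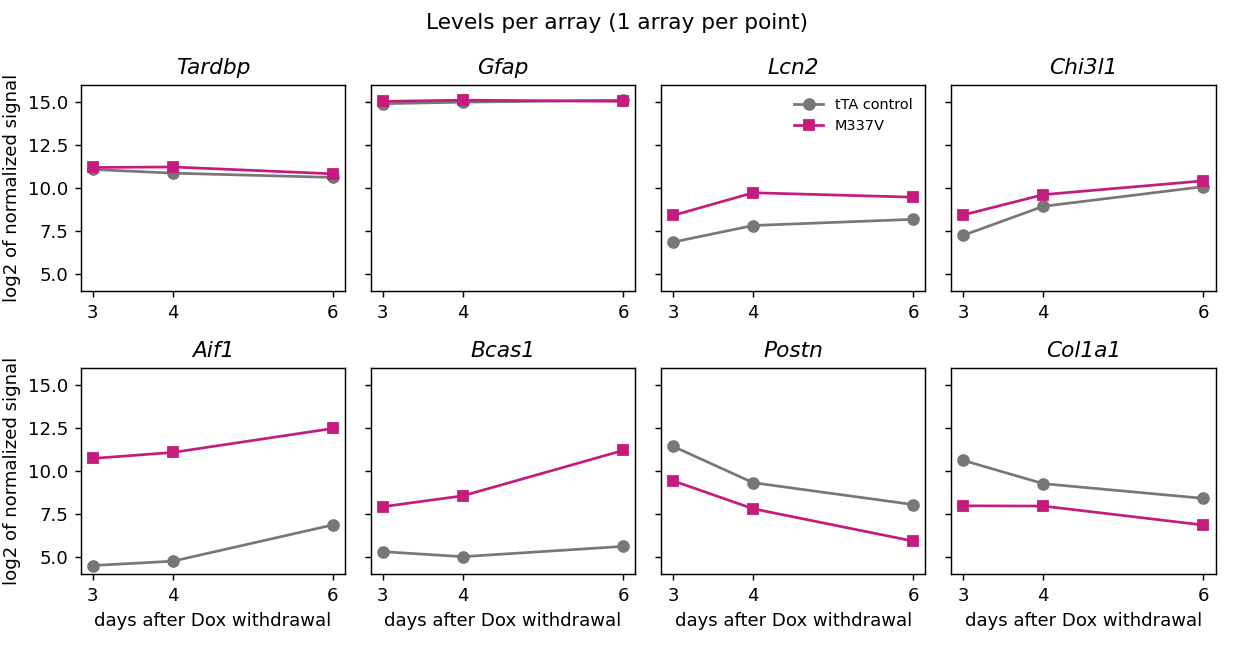
Normalized log2 signal of 8 genes (vertical axis) against days after Dox withdrawal (horizontal axis), 1 array per point, with tTA control arrays as grey circles and M337V arrays as magenta squares. Gfap lies near 15 on every array, Aif1 reads 10.74 to 12.48 in M337V and 4.51 to 6.87 in controls, and Postn goes from 11.44 to 8.05 in controls and from 9.44 to 5.93 in M337V.

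Of the 12 largest rises, 6 were members of the microglia and macrophage list: Aif1, C1qb, Fcer1g, Ctss, C1qc and Trem2. Aif1, which encodes the calcium-binding protein IBA1 of microglia, was at least 55.9-fold higher in M337V (fitted log2 difference 6.06 ± 0.16, SE). The complement chain C1qb (5.94 ± 0.25), the Fc receptor gamma chain Fcer1g (5.73 ± 0.16), the lysosomal protease Ctss (5.64 ± 0.13), the leukocyte actin-bundling protein Lcp1 (5.28 ± 0.12) and the microglial receptor Trem2 (4.80 ± 0.10) followed. Aif1, C1qb, Ctss and Trem2, like Ggcx, were detected on 1 of the 3 control arrays, so their fitted differences rest partly on values below background. With those values at the lowest detected signal, C1qb was at least 46.9-fold, Ctss 42.2-fold, Trem2 26.9-fold and Ggcx 30.5-fold higher. The probes of Pf4, a chemokine, Arhgdib, a gene of blood cells, and C1qc, another C1q chain, were below background on all 3 control arrays, so only bounds can be given: at least 26.5-fold, 21.6-fold and 23.0-fold higher. Besides these, the growth cone gene Gap43 was higher by 4.94 ± 0.15 and Ggcx, the vitamin K-dependent carboxylase, by 5.11 ± 0.10. Pnlip, which encodes pancreatic lipase, was at least 16.4-fold higher. Whether the probes named Ggcx and Pnlip are specific to those genes was not checked. The adjusted p of these 12 genes lay between 5.83e-05 and 0.00381, the latter for C1qc.

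The collagen-binding integrin gene Itga11 fell by 3.57 ± 0.19 on the log2 scale, or 11.9-fold, and Itga1, of the same family, fell by 1.99 ± 0.11. Col8a1, a short-chain collagen, fell by 3.26 ± 0.11, the procollagen protease Adamts2 fell by 2.12 ± 0.15 and the tenascin Tnn fell by 2.10 ± 0.27. Igfbp3, which binds insulin-like growth factors, fell by 2.59 ± 0.14. Cpxm2, a carboxypeptidase-like protein, fell by 2.92 ± 0.14, and Car9, a hypoxia-inducible carbonic anhydrase, fell by 2.40 ± 0.18. Rnf113a2 (-2.97 ± 0.14), Mgst2 (-2.11 ± 0.10), the neuropeptide precursor Npvf (-2.09 ± 0.18) and the serotonin receptor Htr7 (4.0-fold lower) completed the set. Some M337V arrays did not detect Rnf113a2, Car9, Npvf and Htr7, which were at least 6.90-fold, 4.80-fold, 4.22-fold and 3.76-fold lower with those arrays at the lowest detected signal. Their adjusted p lay between 0.000215 (Col8a1) and 0.00725 (Tnn). Without the replicate block, Igfbp3 (adjusted p = 0.0536) and Tnn (0.0601) no longer passed, the highest values over their alternatives, where the lowest were 9.01e-13 and 1.65e-10. Their change from day 3 to day 6 (-2.27 and -1.73) stays in the residual spread of the fit without the block.

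**Figure D2:**
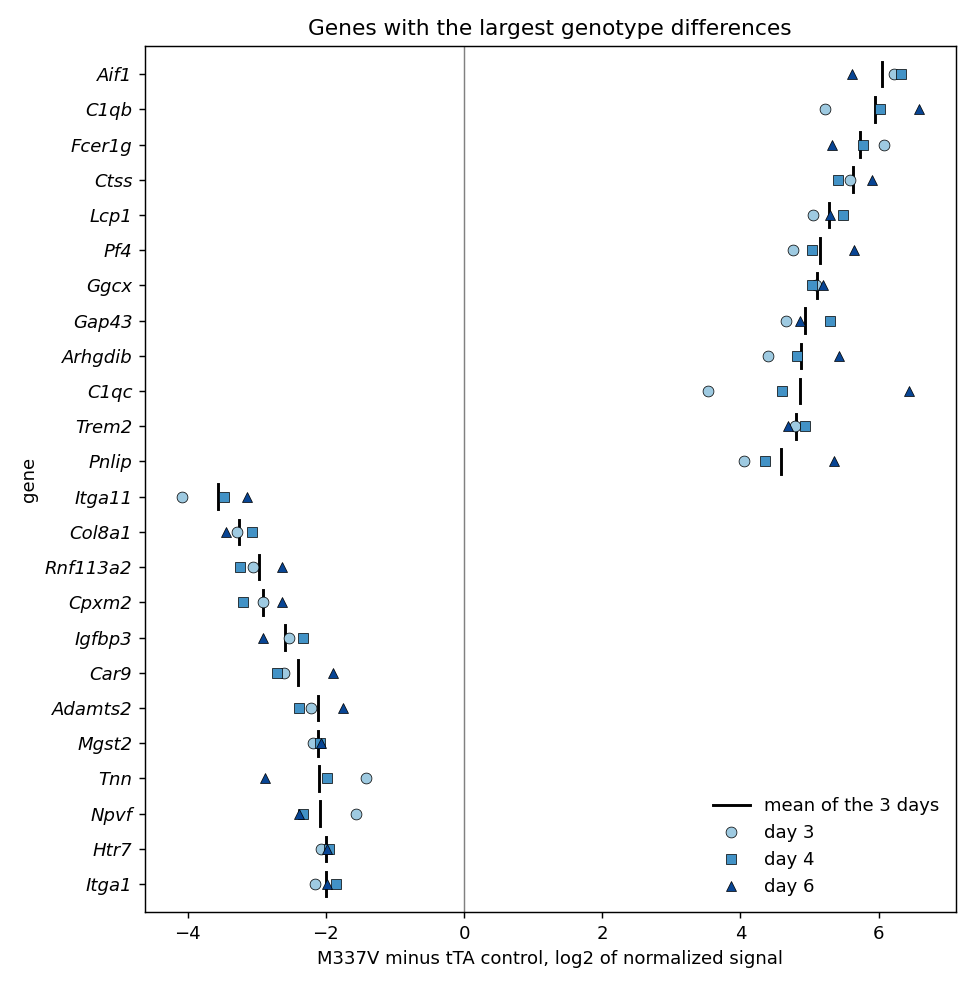
Differences M337V minus tTA control in log2 of normalized signal (horizontal axis) for the 12 largest rises and the 12 largest falls (vertical axis), with 1 symbol per day and a black bar at the mean of the 3 days. Every gene keeps its side of 0 on all 3 days, and the mean runs from 6.06 for Aif1 to -3.57 for Itga11; for Pf4, Arhgdib, C1qc and Pnlip all control probes were below background, and for Aif1, C1qb, Ctss, Trem2 and Ggcx 2 of 3 were.

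Over 7580 genes tested with limma, 739 were higher and 747 lower in M337V at an adjusted p under 0.05, which is 19.6% of the genes. The difference had the same sign on all 3 days for all 1486 of them. Rises were larger than falls, with 321 genes at least 2-fold higher against 129 at least 2-fold lower, and 32 at least 8-fold higher against 2 lower. For 124 of the higher genes no control array was above background, and for 22 of the lower genes no M337V array was. The balance of directions depended on the scaling: 49.7% of called genes were higher here, against 64.5% with median scaling, 59.2% with cyclic loess, 39.7% with the deposited values and 40.9% among probes detected on all 6 arrays. Leaving out a day gave 1055 calls without day 3, 631 without day 4 and 1024 without day 6, and the fit without the replicate block gave 966, of which 953 were among the 1486.

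Markers of other cell types moved with the genotype. Of 19 microglia and macrophage genes tested, 16 rose and none fell, with a median log2 difference of 3.44, or 2.98 when genes without a control signal are set at their bound. Aif1, C1qb, Fcer1g and Ctss led this list, and the median was 2.84, 3.28 and 4.20 on days 3, 4 and 6. It was 1.79 with the deposited values and 1.83 without background correction. Of 10 oligodendrocyte lineage genes, 6 rose and none fell (median 1.21), led by Bcas1 (3.91 ± 0.54), the transcription factor Sox10 (3.24 ± 0.37), the myelin lipid enzyme Ugt8 (2.99 ± 0.47) and the progenitor receptor Pdgfra (2.38 ± 0.24). Sox10 and Ugt8 were detected on 1 control array each and were at least 8.55-fold and 7.59-fold higher. Of 8 cilium genes of ependymal cells 7 rose and none fell (median 1.63), among them Tppp3 (2.16 ± 0.14), Rsph1 (2.12 ± 0.18), Tekt1 (1.72 ± 0.12) and Tekt4 (1.69 ± 0.11). Among 12 neuron genes 6 rose and 1 fell (median 0.49, or 0.35 at the bounds), with Gap43 far ahead of the GABA-synthesizing enzyme Gad1 (2.02 ± 0.16), Syt1 (0.75 ± 0.17) and Ina, at least 1.41-fold higher. Adjusted over the list alone, 17, 6, 7 and 6 members of these 4 lists rose, and 2 neuron genes fell. By limma's camera test with a preset correlation the adjusted p was 1.13e-17 for microglia, 2.99e-05 for the oligodendrocyte lineage, 5.64e-07 for ependymal and 0.00323 for neuron genes. None passed with an estimated correlation, where the adjusted p was 0.261, 0.356, 0.186 and 0.346, and the oligodendrocyte lineage did not pass with fry either (0.0918).

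Of 6 endothelial genes tested, Esam (at least 1.24-fold higher) and Vwf (0.81 ± 0.18) rose and Cldn5 (-0.44 ± 0.11) fell, and the list did not pass (median 0.25, adjusted p = 0.418). Cldn5 lost its call in 13 of 16 alternatives (adjusted p 0.0351 to 0.284; log2 difference -0.15 without background correction), and Vwf lost it in 3 of 16 (0.24 and adjusted p = 0.134 with the deposited values, up to 0.103 with a day left out). The fibroblast and meningeal list went both ways, with 3 members higher and 7 lower of 12 (median -0.55, adjusted p = 0.111). Postn (-1.88 ± 0.15) and Col1a1 (-1.83 ± 0.26) fell, while Igf2 rose (1.86 ± 0.32) and Ptgds differed by at least 2.34-fold without passing (adjusted p = 0.11). That list passed among probes detected on all 6 arrays (adjusted p = 0.000757) and with fry (0.00969), and over its alternatives the adjusted p ran from 0.000757 to 0.437. Of 5 pericyte and smooth muscle genes, the contractile genes Cnn1 (-0.77 ± 0.13), Myl9 (-0.76 ± 0.10) and Tagln (-0.44 ± 0.10) fell, and Mcam was at -0.41 ± 0.13 without passing. This list's adjusted p was 0.0202, then 0.346 with an estimated correlation, 0.0604 without the filter on dim probes and 0.0801 without the replicate block. Counts adjusted over the list alone were 2 higher and 2 lower for endothelial, 4 and 8 for fibroblast and meningeal, and 0 and 4 for pericyte genes.

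Immune genes were higher as groups, in the same arrays in which microglia genes were higher. In the complement list 8 of 12 genes rose and none fell (median 1.19), and after C1qb and C1qc came C1qa, at least 17.0-fold higher, and Cfb, a factor of the alternative pathway (2.97 ± 0.12). Without the members shared with the microglia list, the complement median was 0.95 (adjusted p = 9.68e-06 by camera with the preset correlation). The reduced list was not tested with an estimated correlation. Of 19 interferon response genes 9 rose and none fell (median 0.58), led by the antiviral GTPases Mx1 (2.59 ± 0.10) and Mx2 (2.16 ± 0.10), the chemokine Cxcl10 (1.86 ± 0.16) and Ifi27 (2.83-fold higher). In antigen presentation 9 of 16 rose and none fell (median 0.49). RT1-DMb, which helps load class II molecules, differed by 4.46 ± 0.24, the class I genes RT1-A1 by 1.20 ± 0.09 and RT1-S3 by 1.04 ± 0.10, and RT1-DMa by 1.20 ± 0.24. Adjusted over the list alone, 10 complement, 12 interferon and 10 antigen presentation genes rose. Camera gave adjusted p of 2.96e-08, 5.91e-08 and 3.15e-06 with a preset correlation, and an adjusted p of 0.186 for each of the 3 with an estimated correlation.

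In these arrays with higher microglia genes, cytokine and chemokine genes went both ways, with 10 higher and 4 lower of 20, or 12 and 5 adjusted over the list alone. Ccl3 was at least 3.79-fold higher, Cxcl11 rose by 1.55 ± 0.11 and Spp1, at 1.69 ± 0.46, did not pass (adjusted p = 0.058). Cxcl11 was detected on 1 control array only and was at least 2.39-fold higher with the others at the lowest detected signal. Chosen after their values were seen, the 4 that fell were Cxcl12 (-1.13), Ccl7 (-0.73), Il33 (-0.71) and Ccl2 (-0.51). Ccl2 lost its call in 9 of 17 alternatives (adjusted p 0.00162 to 0.151). The list's median was 0.96, or 0.56 at the bounds, and -0.05 among probes detected on all 6 arrays (adjusted p = 0.705), while the main adjusted p was 0.00337, and 0.346 with an estimated correlation. NF-kappaB feedback genes did not pass as a list (median 0.12, adjusted p = 0.103, but 0.0494 with fry, in a range of 0.0494 to 0.356), with 4 of 12 higher and 1 lower, also adjusted over the list alone. Lcn2, the adhesion molecule Vcam1 (1.01 ± 0.17), the inhibitor Nfkbia (0.79 ± 0.12) and Irf1 (0.64 ± 0.10) were the members with the largest differences.

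In the arrays with higher microglia genes (median 3.44), 4 of 17 mature astrocyte genes rose and 2 fell, or 7 and 2 adjusted over the list alone (median 0.24). The thyroid hormone and organic anion transporter Slco1c1 (-1.16 ± 0.12) and the receptor Fgfr3 (-0.85 ± 0.10) fell, the calcium-binding protein S100b rose (0.93 ± 0.14), and the lipid carrier Apoe, at 0.79 ± 0.24, did not pass (adjusted p = 0.0769). The list's adjusted p was 0.0413, and 0.614 with an estimated correlation, 0.0879 with the deposited values, 0.0959 with cyclic loess, 0.0549 without the replicate block, 0.365 with fry and 0.174 without day 3 (0.0202 to 0.614 over its alternatives). Of 9 neurotoxic (A1) reactive genes 6 rose and 1 fell (median 0.67), or 7 and 1 over the list alone, with members shared with the complement, interferon and antigen presentation lists among the risers. The complement inhibitor Serping1 (2.83-fold), the GTPase Gbp2 (1.20 ± 0.11) and RT1-S3 rose and the elastic fibre gene Fbln5 fell (-0.93 ± 0.10). The A1 list's adjusted p was 0.0013, and 0.356 with an estimated correlation. The pan-reactive list did not pass (4 higher and 1 lower of 14, the same over the list alone, median 0.05, adjusted p = 0.111), except without day 6 (adjusted p = 0.0275, in a range of 0.0275 to 0.578). Cxcl10, Lcn2 and the copper carrier Cp (0.71 ± 0.16) rose, whereas the serpin Serpina3n stood at 0.48 on day 3 and -1.68 on day 6 (mean -0.86 ± 0.41, adjusted p = 0.214). Cp lost its call in 4 of 17 alternatives (adjusted p 0.000373 to 0.38, the latter without the replicate block). Nor did the trophic (A2) list of 6 genes pass (1 higher and 2 lower in both counts, median -0.40, adjusted p = 0.433). Its member Sphk1, a sphingosine kinase, fell by 1.48 ± 0.25, Emp1 fell by 0.88 ± 0.17, Cd14 rose by 0.94 ± 0.15, and Ptgs2 was at -0.60 ± 0.21 (adjusted p = 0.113).

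**Figure D3:**
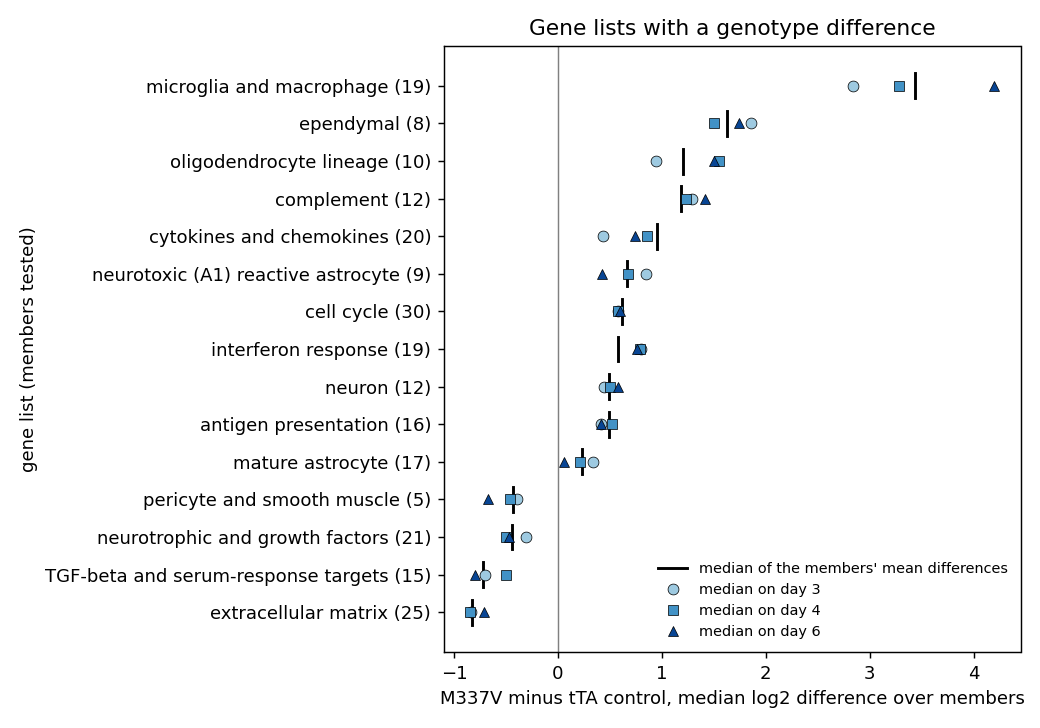
Median log2 difference M337V minus tTA control over the members of the 15 lists that passed camera with a preset correlation (horizontal axis), 1 symbol per day, with a black bar at the median of the members' mean differences; list names and the number of members tested are on the vertical axis. The microglia list stands at 2.84, 3.28 and 4.20 on days 3, 4 and 6, the extracellular matrix list lies lowest at -0.83, and every symbol keeps the side of 0 of its bar.

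Extracellular matrix genes fell as a group, in arrays in which microglia genes were higher and the fibroblast and meningeal list went both ways. Of 25 tested, 17 fell and 2 rose (median -0.83), and 19 fell and 2 rose adjusted over the list alone. After Col8a1, the matricellular protein Postn was 3.68-fold lower, the fibrillar collagen gene Col1a1 3.56-fold lower and the collagen cross-linking enzyme Loxl2 3.48-fold lower. The 2 that rose, named after their values were seen, were the proteoglycan genes Vcan (1.75) and Lum, below background on all control arrays and at least 2.54-fold higher. Of 15 TGF-beta and serum-response targets 11 fell and none rose, or 14 over the list alone (median -0.72). The latent TGF-beta binding proteins Ltbp1 (-1.67 ± 0.19) and Ltbp2 (-1.38 ± 0.10), the matricellular protein Ccn2 (-1.44 ± 0.16) and the stretch-responsive gene Ankrd1 (-1.29 ± 0.24) had the largest falls. Camera gave adjusted p of 5.66e-07 and 6.88e-07 for the 2 lists, and 0.186 and 0.2 with an estimated correlation. Among 18 matrix protease genes 1 rose and 5 fell, or 2 and 5 over the list alone, without a call for the list (median -0.21, adjusted p = 0.11, but 0.0353 without the filter on dim probes, in a range of 0.0353 to 0.483). Adamts5 (-1.10 ± 0.16), Htra1 (-1.01 ± 0.11) and the inhibitor Timp3 (-0.98 ± 0.17) fell, and Plau was at 0.87 ± 0.25 (adjusted p = 0.0694).

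In the same arrays growth factor genes were lower on balance, with 11 of 21 lower and 2 higher, or 12 and 2 over the list alone (median -0.44, adjusted p = 0.00323, and 0.261 with an estimated correlation). Fgf2 fell by 0.84 ± 0.10 and Nrg1, below background on all M337V arrays, was at least 1.65-fold lower. Tgfa (1.99 ± 0.48) and Igf2 rose. The synaptogenic secreted proteins did not pass as a list (1 higher and 3 lower of 9, or 2 and 4 over the list alone, median -0.06, adjusted p = 0.643). Thrombospondin Thbs2 (-1.46 ± 0.23) and the glypican Gpc4 (-0.82 ± 0.10) fell, while Thbs4 (-0.89 ± 0.26, adjusted p = 0.0713) and Apoe did not pass. Glutamate handling showed no list call either (2 higher and 1 lower of 9, or 3 and 1 over the list alone, median 0.13, adjusted p = 0.103, but 0.0448 with fry, in a range of 0.0448 to 0.356). Slc1a1, a glutamate transporter best known from neurons, was 7.63-fold higher (2.93 ± 0.18), the glutamine transporter Slc38a3 rose by 0.85 ± 0.13, Slc38a2 fell by 0.40 ± 0.10, and Got1 was at 0.43 ± 0.12 (adjusted p = 0.063).

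In the arrays in which microglia genes were 3.44 higher as a median, cell cycle genes were higher too, with 21 of 30 higher and none lower, or 22 over the list alone (median 0.61). The mitotic kinase gene Aurkb was 8.12-fold higher (3.02 ± 0.21), ahead of the spindle checkpoint gene Bub1b (1.21 ± 0.14), the replication licensing inhibitor Gmnn (0.93 ± 0.11) and Cdc20 (0.84 ± 0.12). The adjusted p was 2.18e-11, and 0.186 with an estimated correlation.

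Stress lists gave no call here. Of 23 unfolded protein and integrated stress response genes 6 fell and none rose, also over the list alone (median -0.11, adjusted p = 0.0916), with Ddit3 (-0.66 ± 0.13), Ppp1r15a (-0.65 ± 0.15), Asns (-0.56 ± 0.10) and Atf5 (-0.50 ± 0.10) in front. That list did pass with the deposited values (adjusted p = 0.0219), without the filter on dim probes (0.0128), with cyclic loess (0.0395), without background correction (0.0444) and without day 6 (0.0275), and ran from 0.0128 to 0.356 over its alternatives. Of 13 heat shock genes 3 fell and none rose, or 4 and 1 over the list alone: the small chaperones Cryab (-0.70 ± 0.11) and Hspb1 (-0.51 ± 0.10) and the co-chaperone Bag3 (-0.63 ± 0.11), with Hspb8 at -0.49 ± 0.14 (adjusted p = 0.0625). The list's adjusted p was 0.479. Oxidative stress genes split 3 higher and 2 lower of 23 in both counts (adjusted p = 0.257). Gstm1 (0.91 ± 0.10) and Gsta4 (0.82 ± 0.14) rose, and Sod3 (2.01-fold lower) and Hmox1 (-0.79 ± 0.10) fell. Of 15 p53 and apoptosis genes 2 rose and 2 fell, or 2 and 3 over the list alone (median -0.06, mean 0.06, adjusted p = 0.921), led by the inflammatory caspase Casp1, which was 5.42-fold higher (2.44 ± 0.22), and Gadd45a (-0.80 ± 0.13), the kinase inhibitor Cdkn1a (-0.69 ± 0.14) and Casp4 (0.46 ± 0.10).

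Metabolic lists did not pass. In glycolysis and hypoxia 1 of 20 genes rose and 4 fell, or 2 and 5 over the list alone (adjusted p = 0.137). Besides Car9, the hypoxia-inducible genes Adm (-1.40 ± 0.10) and Ndrg1 (-0.96 ± 0.10) fell, and Slc16a3 was at -0.82 ± 0.23 (adjusted p = 0.0607). That list passed with the deposited values (adjusted p = 0.0328) and without the filter on dim probes (0.0401) and with fry (0.044), with a range of 0.0328 to 0.445. Of 15 cholesterol genes 2 fell, or 1 over the list alone (adjusted p = 0.0847): Tm7sf2 (-0.70 ± 0.12) and Sc5d (-0.40 ± 0.09), with Fdps (-0.41 ± 0.12, adjusted p = 0.0629) and Ebp (-0.36 ± 0.12, 0.0918) short of the threshold. The list passed without the filter on dim probes (adjusted p = 0.0341) and without day 6 (0.0275), with a range of 0.0275 to 0.483. None of 20 oxidative phosphorylation genes passed, over all genes or over the list alone (adjusted p of the list = 0.0847), the largest difference being 0.26 ± 0.09 for Sdha. At an unadjusted p under 0.05, 2583 of the 7580 genes differed. The same list passed among probes detected on all 6 arrays (adjusted p = 0.0405) and without the filter (0.0353), with a range of 0.0353 to 0.542.

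Genes tied to TDP-43 and to motor neuron disease differed little. Of 18 RNA-binding partners of TDP-43, Hnrnpa1 rose by 0.43 ± 0.10 and Taf15 fell by 0.43 ± 0.11, and over the list alone none passed. Taf15 lost its call in 8 of 17 alternatives (adjusted p 0.00812 to 0.244) and Hnrnpa1 in 5 of 17 (0.0204 to 0.373), both of them with any day left out. Hnrnpa2b1 (0.38 ± 0.13) and Hnrnpa3 (0.32 ± 0.12) did not pass, nor did the list (median 0.11, adjusted p = 0.0919), except without day 6 (adjusted p = 0.0461, in a range of 0.0461 to 0.624). None of 15 motor neuron disease genes passed in either count (median -0.09, adjusted p of the list = 0.496), with Tuba4a at -0.27 ± 0.10, Grn at -0.25 ± 0.15 and Sqstm1 at -0.23 ± 0.10. Of 22 autophagy and lysosome genes 2 rose and 1 fell in both counts (median -0.13, mean 0.14, adjusted p = 0.512). These were Ctss, Ctsb (0.56 ± 0.10) and Ctsl (-0.64 ± 0.11), with Ctsd at -0.43 ± 0.12 (adjusted p = 0.06).

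Of the 128 genes named here that were called for the genotype, 59 lost the call in at least 1 alternative. This was judged by the adjusted p alone, so the minimum log2 difference, though among the alternatives, could end no call. Without the replicate block 38 did, among them Postn (adjusted p = 0.298), Slco1c1 (0.188), Gstm1 (0.185), Serping1 (0.16), RT1-S3 (0.152) and Myl9 (0.134). Cldn5, Taf15, Hnrnpa1, Sc5d, Slc38a2, Tagln, Casp4 and Ccl2 lost it with each of the days left out.

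Across the 33 lists, 11 were called higher and 4 lower with the preset correlation, and none with a correlation estimated from these arrays, where the smallest adjusted p was 0.186. The preset test also called 5 to 15 lists in each of the 9 other groupings of the 6 arrays into 3 and 3, in which no gene was called. Each of these groupings mixes arrays of both genotypes, so part of the genotype difference stays in the contrast and part enters the residual. Neither count is therefore a rate of calls without a genotype difference.

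The second question was how the genotypes compared on each day, where 1 array per genotype allows no test. On day 3, 324 genes were at least 2-fold higher and 184 lower in M337V, of 7885 detected on either array. Day 4 had 333 higher and 136 lower of 8144, and day 6 had 428 higher and 175 lower of 8298. Between control arrays of different days the same count was 43 higher and 44 lower from day 3 to 4, 25 and 17 from day 4 to 6, and 128 and 115 from day 3 to 6. Between M337V arrays it was 43 and 21, 95 and 17, and 242 and 80. A total of 222 genes were at least 2-fold higher on all 3 days and 63 lower. The largest rises on day 3 were Aif1 (at least 53.1-fold), Fcer1g (67.6-fold) and Ctss (at least 34.9-fold). On day 4 they were Aif1 (at least 67.2-fold), C1qb (at least 43.0-fold) and Fcer1g (54.7-fold), and on day 6 C1qb (95.7-fold), C1qc (at least 74.1-fold) and Ctss (59.9-fold). The place of C1qb on day 4 rests on a control value below background, and Lcp1 (log2 difference 5.49) rose by more than its bound. Itga11 (17.0-fold), Col8a1 (9.71-fold) and Rnf113a2 (at least 7.31-fold) were the most lowered genes on day 3 by normalized signal. The place of Rnf113a2 rests on a value below background, and Cpxm2 (log2 difference -2.92) fell by more than its bound. Itga11 (11.1-fold), Rnf113a2 (at least 7.28-fold) and Cpxm2 (9.19-fold) followed on day 4, and Col8a1 (10.9-fold), Itga11 (8.84-fold) and Igfbp3 (log2 difference -2.91) on day 6. On day 4 too Col8a1 (log2 difference -3.06) fell by more than the bound of Rnf113a2. These counts depended on the treatment of dim signals, and without background correction they were 120 higher and 66 lower on day 3, 137 and 54 on day 4, and 215 and 62 on day 6.

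The third question was whether the genotype difference changed with the time of induction. The difference of Bcas1 went from 2.62 on day 3 to 3.54 on day 4 and 5.58 on day 6, a slope of 0.99 ± 0.08 per day (SE). The slope was 0.89 ± 0.09 per day for the growth factor Tgfa and 0.69 ± 0.08 for the secretory pathway gene Gask1b. C1qc and the chemokine Ccl6 also had small p-values, but no control array detected them, so their slopes are not determined. Negative slopes were found for the granin Scg2 (-0.92 ± 0.09), the opioid peptide precursor Pnoc (-0.60 ± 0.09), Tnn (-0.48 ± 0.08), the synaptic adhesion gene Slitrk1 (-0.47 ± 0.08) and the urea cycle enzyme Ass1 (-0.45 ± 0.08). No gene passed with limma (smallest adjusted p = 0.114), while 741 had an unadjusted p under 0.05, 436 of them with a positive slope. This count rested on 1 residual degree of freedom and on the setting: 189 genes were called with the deposited values, 195 with median scaling, 235 without background correction, 254 with an offset of 50 and 193 with a variance trend. Of the other 7 settings, 5 called 0 genes, cyclic loess among them, the fit without the filter called 1 and that on probes detected on all 6 arrays 8. Among the 5 settings with over 50 calls, 100 genes were called in each, 97 with a positive slope. These settings were picked by their number of calls. The shared genes include C1qc, Ccl6 and Pnlip, which no control array detected, so the count holds slopes that are not determined.

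The fourth comparison was the change from day 3 to day 6 in both genotypes, against which the genotype differences of a day are read. Tf, the iron carrier transferrin, was higher on day 6 by 2.61 ± 0.23 (SE), Chi3l1 by 2.41 ± 0.21, the BMP antagonist Chrdl1 by 2.34 ± 0.27, Aif1 by 2.06 ± 0.20, the cilium gene Cfap126 by 2.05 ± 0.28 and the integrin gene Itgb4 by 2.0 ± 0.12. Postn fell by 3.45 ± 0.18, the muscle carbonic anhydrase Car3 fell by 3.09 ± 0.27, Igfbp3 fell by 2.27 ± 0.17, the actin gene Acta1 fell by 2.27 ± 0.18, Col3a1 fell by 1.77 ± 0.15 and the neuropeptide Npy fell by 1.74 ± 0.15. Only genes with the same sign in both genotypes could be named here, so that agreement is no result. Aif1 was below background on 2 of the 3 control arrays, and the adjusted p of the 12 lay between 0.0205 and 0.0362. In all, 131 genes were higher and 84 lower on day 6, with 1701 genes at an unadjusted p under 0.05. The counts rose to 552 higher with median scaling and to 498 higher and 429 lower with a variance trend.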

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

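Of the tests in this part, all but the other groupings of the arrays for the count of genes were chosen only after results were seen. For 2 genes the genotype difference was at least 2-fold in opposite directions on 2 days: the chemokine Ccl20 (1.63 on day 4 and -1.07 on day 6, log2) and the granin Scg2 (1.17 on day 3 and -1.66 on day 6). This opposition between days was not tested, since each day has 1 array per genotype. Among probes that do not have exactly 1 gene symbol, a set left out of the comparisons, 381 of 2767 were called for the genotype (13.8%). Of these, 205 were higher and 176 lower, with log2 differences from -2.43 to 5.20.

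Microglia, oligodendrocyte lineage and ependymal lists were higher in the M337V arrays with the preset correlation (adjusted p = 0.261, 0.356 and 0.186 with an estimated correlation). Fewer astrocytes, with the other cells kept in proportion to each other, would raise markers of all other cells alike. The fibroblast and meningeal median was instead -0.5478 (SD of the members 1.36), with 7 of 12 members lower. The microglia median was 3.439, a gap of 3.40 to 4.71 over the days. The fibroblast and meningeal list shares collagen genes and Postn with the matrix list, which fell. Its 7 members outside the matrix and TGF-beta lists had a median of -0.3738, with 2 higher and 3 lower. They did not rise as the microglia genes did, but they do not settle the share of astrocytes. A larger share of microglia would also lower the share of astrocytes, without raising fibroblast genes. Normalization or background correction leaves the microglia median at 1.787 or more in all the normalizations run. Whether the cultures differed in their number of microglia or in the expression of these genes per cell was not tested. No array before induction was analysed here, so a difference that preceded the transgene also stays open.

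Extracellular matrix and TGF-beta lists were lower with the preset correlation (adjusted p = 0.186 and 0.2 with an estimated correlation). Dilution by other cells as the whole account would lower all astrocyte genes by about as much, but the mature astrocyte median was 0.2364 (SD of the members 0.557) against -0.8305 for the matrix list (SD 1.05), a gap of 0.776 to 1.18 over the days. Over the other normalizations the matrix median stayed between -0.8603 and -0.6308. Fewer fibroblast and meningeal cells could not be judged: the 7 list members outside the matrix and TGF-beta lists had a median of -0.3738, with 2 higher and 3 lower. Lower expression of matrix genes in the M337V astrocytes themselves remains a hypothesis.

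The genotype difference correlated weakly with the change with day. Across 7580 genes the difference on day 4 correlated at 0.219 with the controls' change from day 3 to day 6, which shares no array with it (Spearman 0.128). The day 3 and day 6 differences correlated at 0.167 and 0.137 with the controls' changes from day 4 to 6 and from day 3 to 4, and genes are not independent replicates. For day 4 the lowest value over the other normalizations was 0.2188, so the normalization or background correction methods run did not remove it. M337V cultures further along in culture time could not be the whole account, since the cell cycle median was 0.6146 for the genotype and -0.6516 for the controls' change from day 3 to day 6.

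The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1486 genes and the highest other split 0, so 1 of 10 reached the real count. Every other split mixes arrays of both genotypes in each group. The genotype difference then enters the residual spread, so a low count of genes in those splits was built in. For lists tested with the preset correlation the real split called 15 and the highest other 15, so 3 of 10 reached it. Among the 4 splits that part each day's pair, the real one called 15 lists and the others 5 to 9. Part of the genotype difference also stays in the contrast of the other splits, so their list counts are no rate of calls without a difference.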

How the results depend on the processing

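Of 128 named genes called for the genotype, 1688 of 1763 values under the alternatives kept direction and threshold, 75 fell short of the threshold and 0 reversed; with a day left out these were 311, 73 and 0 of 384. The 1763 values include the minimum log2 difference and the looser threshold, which could end no gene's call. Of 132 values of called lists 109 kept both, and of 161 values of lists not called 140 did, with 15 passing. Testing every detected probe and removing microglia members from the lists were chosen after the data were seen. Probes near background limit the sizes of dim genes, and too few microglia, pericyte and endothelial genes were detected on all 6 arrays for a list test there. Leaving out a day leaves 2 arrays per genotype. For the values below, the cause was not tested.

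Genes higher and lower by genotype (739 and 747) became 321 and 129 at a log2 difference of at least 1. Lower genes were 1121 with the deposited values, 441 with median scaling, 470 without the replicate block and 1185 at an adjusted p under 0.10. Leaving out a day gave 384 to 583 higher and 247 to 472 lower. Genes higher and lower with day (131 and 84) were 429 and 362 without background correction, 423 and 275 with the deposited values, 330 and 267 with an offset of 50, 262 and 231 detected on all 6 arrays, 498 and 429 with a variance trend, 378 and 299 at 0.10, and 552 higher with median scaling. Slopes called (0 with limma, 741 at an unadjusted p under 0.05) were 235 without background correction, 189 with the deposited values, 195 with median scaling, 254 with an offset of 50, 1 without the filter, 8 detected on all 6 arrays and 193 with a variance trend.

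Genes 2-fold higher and lower were, on day 3, 120 and 66 without background correction, 107 and 83 with the deposited values, 179 and 92 with an offset of 50, 809 and 824 at 1.5-fold, 187 higher when detected on all 6 arrays and 280 lower with median scaling. On day 4 they were 137 and 54, 128 and 57, 205 and 79, and 714 and 665 in the first 4 of these settings, and 183 higher when detected on all 6 arrays. On day 6 they were 215 and 62, 203 and 75, and 833 and 778 without background correction, with the deposited values and at 1.5-fold, with 221 higher when detected on all 6 arrays, and 98 (median scaling) and 90 (offset of 50) lower. With an estimated correlation 0 lists were higher and 0 lower, and without the filter 7 were lower. Signs reversed for Gfap (-0.1072 deposited, -0.02854 median scaling) and for some settings of Slitrk1, Npy, Scg2 and Pnoc, whose genotype differences were not called. Slitrk1 (0.034 in the main fit) was -0.06733 deposited and -0.258 and -0.07344 without day 3 and day 4, but kept its sign without day 6 (0.434). Npy (-0.099 in the main fit) was 0.02554 with median scaling and 0.04067 without day 3, but kept its sign without day 6 (-0.1866). Scg2 (-0.19 in the main fit) was 0.5457 without day 6, but kept its sign without day 3 (-0.8684). Pnoc (-0.47 in the main fit) was 0.00484 without day 6, but kept its sign without day 3 (-0.9174). List medians reversed for pan-reactive (-0.05078), oxidative stress (-0.003772) and oxidative phosphorylation (-0.0452) with the deposited values. They also reversed for A2 (0.01675) without the filter, and for synaptogenic (0.02395) and heat shock (0.0008228) with cyclic loess. The cytokine median was -0.05233 when detected on all 6 arrays.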

Other observations

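The list tests of the change with day were chosen after results were seen. From day 3 to day 6, over both genotypes, cell cycle genes fell, with 11 of 30 lower and none higher, or 21 adjusted over the list alone (median -0.76). The mitotic kinesin Kif20a (-1.20), the cyclins Ccnb2 (-1.13) and Ccna2 (-1.08) and the nucleotide reductase subunit Rrm2 (-1.08) were among them. Of 25 extracellular matrix genes 5 fell, or 18 over the list alone (median -0.63), with the cross-linking enzyme Lox at -1.70. Of 15 cholesterol synthesis genes 4 fell, or 10 over the list alone (median -0.56), namely Fdps (-1.16), Cyp51 (-1.07), Idi1 (-1.07) and Tm7sf2 (-0.93). Camera gave adjusted p of 2.06e-12, 8.51e-10 and 8.82e-08, and adjusted p = 0.264, 0.264 and 0.39 with an estimated correlation.

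Complement genes rose with day, 5 of 12, or 9 over the list alone (median 1.07), among them the inhibitor Serping1 (1.92), C4b (1.17) and C2 (0.93). Of 19 microglia genes 5 rose, or 6 over the list alone (median 0.79), but Aif1, C1qb, Ctss and Trem2 among the 5 were detected on only 1 of the 3 control arrays. Of 8 ependymal genes Tppp3 (1.47) and Dnali1, below background on 1 control array, rose, or 6 over the list alone (median 0.70). The adjusted p were 2.06e-08, 4.71e-07 and 0.000562, and adjusted p = 0.264, 0.463 and 0.39 with an estimated correlation. Camera called 11 of 33 lists for the day effect, and 0 with an estimated correlation.

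Camera on the slope, also chosen after results were seen, called 4 lists, and 0 with an estimated correlation. It gave a median of 0.28 per day for microglia (adjusted p = 7.81e-09) and 0.30 per day for the oligodendrocyte lineage (1.85e-07). The slope median was -0.12 per day for the mature astrocyte list (0.0305) and -0.12 for the pan-reactive list (0.0403), and adjusted p = 0.811 for each of the 4 with an estimated correlation. Several microglia members were below background on most control arrays, which leaves their slopes undetermined.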
